A study of Mus musculus with 47 samples.

How the data were processed

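Polyadenylated RNA of 47 mouse libraries was measured by strand-specific RNA sequencing, and the values used are the deposited TPM, one value per gene symbol and library. Per the submitters' processing notes, reads were aligned with STAR 2.6.1d to mm10; the counting tool and the gene annotation are not given in the sources used here. Each library summed to 1000000 over 35856 gene symbols, of which 27296 were above 0 in at least 1 library, and every column was used. The symbols were matched to GENCODE M21 on GRCm38, which is mm10, for coordinates and chromosome; 26704 symbols matched 1 gene.

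Low TPM values of a gene were whole multiples of 1 step per gene and library. Whole reads were recovered from these steps for 100% of genes above 0, within a tolerance of 0.001 of a whole number, and their sums give the depth of 3.24 to 8.71 M reads per library (M, 1000000). The length implied by the steps and the annotated exon length had a Spearman rho of 0.781 over 18030 genes, across genes and not replicates. The 10 most abundant genes took 4.91% to 6.72% of TPM in a library. Replicates of a group differed by more than counting error, with a chi-square per degree of freedom of 1.072 to 3.764, and 0 pairs of libraries were identical. At this depth a gene near 1 TPM rests on few reads, so read numbers are given for the lowest genes; they carry counting error only where PCR copies are absent.

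Groups were taken from the labels: line (untagged, SUZ12, MTF2, JARID2), stage (ESC or NPC) and treatment. ESC were kept with 100 U/ml LIF, 3 µM CHIR99021 and 1 µM PD0325901, and NPC were made with 10 ng/ml bFGF for 72 hours followed by 500 nM of the Hedgehog agonist SAG for 48 hours. Auxin was 50 µM indole-3-acetic acid for 12 hours in ESC or 5 days in NPC. Titles of the MTF2 and JARID2 NPC libraries name day 0, while their other labels name NPC and 5 days, and the latter were followed. The replicate numbers 1 and 2 in the titles of SUZ12 NPC with auxin are 2 and 3 in the library names. The series design states biological replicates.

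Genes at 1 TPM or more in at least 2 libraries of a stage were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend and robust) on log2(TPM + 0.5), with all 8 groups of a stage in 1 fit. Stage comparisons used all 16 groups in 1 fit with the filter over all libraries. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Every adjusted p given for a gene is limma's, two-sided. Each auxin group was compared with the untreated group of its own line and stage, untagged NPC with untagged ESC, each tagged line with the untagged line without auxin, and differences of effects were tested as contrasts. Of each line's auxin effect, the part beyond the untagged line was tested by subtracting the untagged contrast. Shares of sign and change kept there are over genes called in the auxin comparison itself, a choice that favours keeping them.

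In total 29 gene lists were written from general knowledge and tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, when 5 or more members were tested; an estimated correlation and fry were alternatives. They were the subunits of PRC2 and PRC1, Hox genes, other Polycomb-target developmental regulators, naive and general pluripotency, formative epiblast, neural progenitor, Hedgehog and ventral neural tube, neurons, mesoderm, endoderm, trophectoderm, neural crest, two-cell-like, germ line, imprinted genes, cell-cycle inhibitors (a list that also holds the cyclin genes Ccnd1 and Ccnd2), proliferation, p53 response, amino acid and unfolded protein stress, aryl hydrocarbon receptor, ERK and FGF, WNT, retinoic acid, TGF-beta, DNA methylation, glycolysis and cholesterol synthesis. Some genes belong to several lists. Sets of up to 300 genes with the largest rise or fall in differentiation, and genes called higher in the SUZ12 line, were tested in the other comparisons with camera, adjusted over the sets of a comparison. Overlaps of calls were tested per direction with a one-sided Fisher exact test, which counts genes as independent draws.

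Named genes are the 10 called genes with the largest rise and the 10 with the largest fall in each auxin comparison and in differentiation (5 and 5 in comparisons of differences or of untreated lines), among genes whose compared groups do not overlap in the former, leaving out unnamed gene models; up to 4 called members of a list with the smallest p, or 2 given as values where none was called; and Suz12, Mtf2 and Jarid2. Chance alone separates 3 libraries from 3 for 10% of genes. Some of the largest changes are microRNA, small nuclear or histone genes with few reads, and the text gives the others first. Some genes that the rule names are not reported here. The groups, comparisons, tests, lists, naming rule and most alternatives were fixed before the data were examined.

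Alternatives were pseudocounts of 0.1 and 1, no filter, median-of-ratios scaling, a fit to the compared groups alone, replicate number as a block, a change of at least 2-fold, sets of 100 genes, leaving out each library in turn and subtraction of the untagged effect. The block was fitted to the compared groups alone. After seeing the data, voom on the recovered reads, a test without very short genes and, for untreated NPC, sets chosen in the auxin libraries of the untagged line were added. The method was tested on simulated data with 200 changed genes per comparison: at 1.5-fold 46.3% to 64.2%, at 2-fold 67.2% to 77.6% and at 4-fold 78.8% to 93.9% were recovered over the 8 auxin comparisons, 0 in the wrong direction, and 2.5% to 12.8% of calls were false. A planted list of 30 genes at 1.5-fold was called in each of the 8 comparisons by camera, with 0 other lists. Genes were simulated independently and the other lists were random genes, so false calls from correlated genes could not be measured. Tables were prepared with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures with matplotlib 3.10.9. Protein levels and chromatin were not analysed here.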

Results

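Polyadenylated RNA was sequenced from mouse embryonic stem cells (ESC) and from neural progenitor cultures (NPC) made from them. All 4 lines were of C57BL/6 background and expressed Tir1, the plant F-box protein that marks degron-tagged proteins for destruction when auxin is present. One line carried no degron, and the other lines carried an auxin-inducible degron on SUZ12, MTF2 or JARID2. SUZ12 is a core subunit of the histone methyltransferase complex PRC2, and MTF2 and JARID2 belong to its alternative accessory forms. Each line was collected untreated and with 50 µM auxin, for 12 hours in ESC and throughout the 5 days of differentiation in NPC. The 47 libraries formed 16 groups of 3 biological replicates, except SUZ12 NPC with auxin, which had 2. In all, 24 libraries came from ESC and 23 from NPC.

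Recovered depth was 3.24 to 8.71 M reads per library (M, 1000000), with a median of 5.39 M. Untagged ESC had 5.27 to 5.5 M reads untreated and 5.42 to 6.17 M with auxin, and SUZ12 ESC 7.3 to 8.71 and 5.39 to 6.5 M. MTF2 ESC had 3.24 to 5.2 and 4.61 to 5.08 M, and JARID2 ESC 4.24 to 5.76 and 3.76 to 5.05 M. For NPC the ranges were 6.34 to 8.03 and 4.15 to 6.88 M in the untagged line and 6.59 to 7.7 and 5.63 to 6.3 M in the SUZ12 line. They were 3.62 to 5.66 and 3.49 to 4.93 M in the MTF2 line and 4.92 to 6.23 and 4.73 to 5.54 M in the JARID2 line. Between 13018 and 14728 genes reached 1 TPM in a library. Values below are mean TPM ± SD with n = 3, or n = 2 for SUZ12 NPC with auxin. Changes are limma log2 fold changes ± SE on log2(TPM + 0.5), a scale that understates changes of genes near 0.

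The degron acts on protein, so the RNA of the targeted genes was examined for the level of the transcript itself. Suz12 (chromosome 11, 79993106 to 80034123, GRCm38), Mtf2 (chromosome 5, 108065674 to 108109004) and Jarid2 (chromosome 13, 44729474 to 44921643) did not pass the test for auxin in any ESC line. In the line tagged on the same protein, Suz12 RNA in ESC was 313 ± 11.2 TPM with auxin and 285 ± 29.5 TPM untreated (adjusted p = 0.35). Mtf2 RNA in ESC was 56.2 ± 0.983 and 52.1 ± 4.8 TPM (adjusted p = 0.636), and Jarid2 RNA was 94.6 ± 6.37 and 95.6 ± 3.97 TPM (adjusted p = 0.967). In NPC, Suz12 RNA of the SUZ12 line rose with auxin from 77.8 ± 1.5 to 163 ± 5.09 TPM (log2 1.06 ± 0.12, adjusted p = 1.01e-07). Jarid2 RNA of the JARID2 line rose from 35.6 ± 3.31 to 56.6 ± 7.36 TPM (0.66 ± 0.09, adjusted p = 5.3e-06). That rise was not particular to the JARID2 degron: in SUZ12 NPC Jarid2 RNA was 38.3 ± 2.04 TPM untreated and 69 ± 5.75 TPM with auxin. Mtf2 RNA of the MTF2 line was 21.1 ± 0.547 TPM untreated and 24.3 ± 2.56 TPM with auxin (adjusted p = 0.153).

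To describe the differentiation itself, untreated NPC of the untagged line were compared with untreated ESC of that line. The pluripotency factor gene Nanog (chromosome 6, 122707489 to 122714633) fell from 737 ± 10.5 to 3.5 ± 0.306 TPM (log2 -7.53 ± 0.15, adjusted p = 2.22e-31). Pou5f1 (chromosome 17, 35506018 to 35510772), which encodes OCT4, fell from 1730 ± 46.7 to 11.2 ± 1.34 TPM (-7.21 ± 0.08, adjusted p = 1.7e-40). The growth factor gene Fgf4 fell by 8.14 on the log2 scale, the threonine dehydrogenase gene Tdh by 8.58 and the aquaporin gene Aqp3 by 8.69. The ventral neural tube regulator gene Nkx6-1 (chromosome 5, 101658139 to 101664996) reached 644 ± 56.3 TPM against 3 reads in the 3 ESC libraries. Neurofilament gene Nefm rose by 8.30 ± 0.27, and the imprinted neuronatin gene Nnat rose by 9.19 ± 0.27 to 1340 ± 12.4 TPM. Fabp7, a radial glia fatty acid binding protein, was listed at 0 in all 3 ESC libraries and measured 263 ± 17.6 TPM in NPC.

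All 20 naive pluripotency genes fell (median log2 -6.52, camera adjusted p = 1.94e-18), and of 15 general pluripotency genes 14 fell and 1 rose (adjusted p = 8.51e-10). Of 34 germ line and meiosis genes, 29 fell and 1 rose (adjusted p = 5.37e-10), and Dazl fell by 5.55. Of 16 two-cell-like genes, 15 fell and 0 rose (adjusted p = 0.000199). Among 30 neuron genes 28 rose and 2 fell (median 4.93, adjusted p = 4.48e-11). Among 41 neural progenitor genes 33 rose and 8 fell (median 3.61, adjusted p = 3.32e-06), Nes by 5.01 ± 0.07. Ventral neural tube and Hedgehog genes rose in 15 of 19 cases and fell in 3 (adjusted p = 0.00183, adjusted p = 0.0745 with an estimated correlation). Polycomb-target developmental regulators other than Hox rose in 78 of 125 and fell in 22 (adjusted p = 0.00831, adjusted p = 0.0786 with an estimated correlation). All 10 genes of the cell-cycle inhibitor list, which also holds the D-type cyclin genes Ccnd1 and Ccnd2, rose, Cdkn1c by 5.82 ± 0.13 and Ccnd1 by 2.26 ± 0.04 (adjusted p = 0.000756). Cholesterol synthesis genes rose in 17 of 20 and fell in 1 (adjusted p = 0.000471). PRC2 subunit genes fell in 7 of 12 and rose in 3 (adjusted p = 0.0337, adjusted p = 0.387 with an estimated correlation). Suz12 fell from 145 ± 3.08 to 36.9 ± 1.08 TPM (-1.96 ± 0.10), Jarid2 from 112 ± 2.4 to 38.5 ± 2.43 TPM and Mtf2 from 65.1 ± 2.56 to 23.6 ± 0.901 TPM. Hox genes, 15 of 32 higher and 8 lower, did not pass as a list (adjusted p = 0.299), nor did PRC1 subunits, 14 of 23 higher and 6 lower (adjusted p = 0.468).

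In all, 13517 of 17760 tested genes passed in this comparison, 8462 higher and 5055 lower, and 7821 also changed at least 2-fold. The median gene shifted by 0.283 log2, so a change is relative to that shift. Also lost with an estimated correlation were the calls of the imprinted (29 of 39 higher, 9 lower, adjusted p = 0.246), proliferation (5 of 26 higher, 17 lower, adjusted p = 0.089) and WNT (5 of 18 higher, 11 lower, adjusted p = 0.0606) lists. Median, mean and test differed in sign for the formative epiblast, mesoderm, endoderm, ERK and FGF, TGF-beta and unfolded protein stress lists, none of which passed.

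Auxin itself was controlled with the untagged line, which has no protein to degrade. In ESC after 12 hours, Spry4 (chromosome 18, 38586247 to 38601415), a feedback inhibitor of receptor tyrosine kinases, fell from 3.61 ± 0.053 to 1.35 ± 0.292 TPM (log2 -1.16 ± 0.14, adjusted p = 0.000128). The ETS factor gene Etv4 fell from 55.1 ± 0.372 to 38.6 ± 3.95 TPM (adjusted p = 0.00734). Utf1 (chromosome 7, 139943789 to 139945112), a chromatin factor of pluripotent cells, fell from 381 ± 6.24 to 235 ± 7.72 TPM (-0.70 ± 0.04, adjusted p = 9.2e-10). The BMP targets Id3 and Id1 fell by 0.55 and 0.77 on the log2 scale. Cyp1a1 (chromosome 9, 57687928 to 57703824), the cytochrome P450 gene induced by the aryl hydrocarbon receptor, was 0.146 ± 0.00398 TPM (3 reads) untreated and 1.44 ± 0.691 TPM (32 reads) with auxin (adjusted p = 0.023). The quinone reductase gene Nqo1 rose by 0.30. Small rises were also seen for the cell-cycle inhibitor gene Cdkn1a (0.25, from 163 ± 1.76 to 194 ± 3.52 TPM), Aqp3 (0.25 ± 0.03) and the phospholipase gene Plcg2 (0.40).

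Of 18 ERK and FGF target genes in untagged ESC, 2 fell and 0 rose, with 5 lower adjusted over the list alone (camera adjusted p = 7.19e-12). General pluripotency genes fell in 2 of 15, or 6 adjusted over the list alone (adjusted p = 7.23e-10). TGF-beta, NODAL and BMP genes fell in 2 of 19 (adjusted p = 0.000412). The aryl hydrocarbon receptor list had 2 of 12 higher (adjusted p = 0.00986, adjusted p = 0.323 with an estimated correlation). Formative epiblast genes had 0 called members, with 1 lower adjusted over the list alone (adjusted p = 0.000365). Calls of the naive pluripotency (adjusted p = 0.476), germ line (0.323), DNA methylation (0.335) and glycolysis (0.0646) lists were lost, each value being the adjusted p with an estimated correlation. Among 15104 genes 32 passed, 9 higher and 23 lower, of which 2 changed at least 2-fold. The count was 18 without untreated replicate 3 and 19 without auxin replicate 1, 2 or 3, and voom on recovered reads, chosen after seeing the data, called 57.

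In NPC of the untagged line after 5 days of auxin, 0 of 16469 genes passed in limma, while 1180 had an unadjusted p under 0.05, and voom called 16. The neuronal growth cone gene Gap43 was 265 ± 9.4 TPM with auxin and 317 ± 10 TPM untreated (adjusted p = 0.229), and the neurofilament gene Nefl 866 ± 22.2 and 1070 ± 37.5 TPM (adjusted p = 0.361). As a list, 30 neuron genes were lower by a median of -0.20, with 10 lower adjusted over the list alone (adjusted p = 2.11e-11, adjusted p = 0.0619 with an estimated correlation). Cholesterol synthesis genes were lower by a median of -0.10 (adjusted p = 0.0619 with an estimated correlation). Lists of glycolysis, proliferation and aryl hydrocarbon receptor genes were higher by medians of 0.09, 0.04 and 0.06. Their adjusted p with an estimated correlation was 0.34, 0.314 and 0.0619. Without auxin replicate 2 the count was 1, and without auxin replicate 3 it was 2; a fit to these 6 libraries alone called 4.

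**Figure D1:**
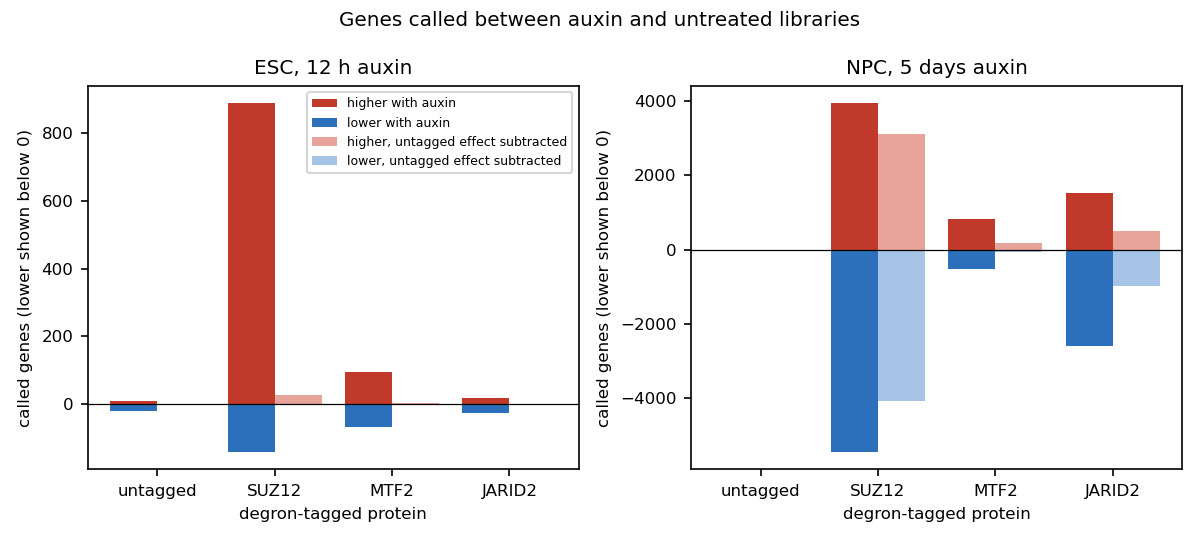
Genes called between auxin and untreated libraries, number of genes on the y axis (lower genes drawn below 0), by line on the x axis, for ESC on the left and NPC on the right. Dark bars are the direct comparison and pale bars the same comparison with the change of the untagged line subtracted; in NPC the SUZ12 line had 9368 calls, or 7170 after subtraction.

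What auxin changes in SUZ12 degron stem cells within 12 hours was examined next. The developmental zinc finger gene Sp8 (chromosome 12, 118846329 to 118852576) rose from 0.821 ± 0.379 to 2.6 ± 0.333 TPM (log2 1.26 ± 0.24, adjusted p = 0.00318). The organizer gene Gsc rose from 24.2 ± 2.4 to 43.2 ± 2.34 TPM (0.83 ± 0.15), and the simple epithelial keratin gene Krt7 rose by 1.24 ± 0.28. The germ cell RNA-binding protein gene Dazl rose from 53.7 ± 3.15 to 83.9 ± 6.03 TPM (0.64 ± 0.09, adjusted p = 0.000168). Pramel6 (chromosome 2, 87506565 to 87510872), expressed in naive stem cells, fell from 5.79 ± 1.14 to 1.44 ± 0.697 TPM (-1.75 ± 0.24, adjusted p = 0.000168), and the growth factor gene Bmp4 from 4.52 ± 1.11 to 2.13 ± 0.292 TPM (-0.91 ± 0.21). Cyp1a1 rose from 0.259 ± 0.0728 to 2.74 ± 0.475 TPM, and Spry4 and Utf1 fell by 0.92 and 0.62, the directions seen without a degron.

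Of 70 Polycomb-target developmental regulators expressed in ESC, 12 rose and 0 fell, with 16 higher adjusted over the list alone (median 0.45, adjusted p = 0.000127). Besides Gsc these included Msx2 (0.95), Tlx2 (0.91) and Pitx1 (0.97). Germ line genes rose in 7 of 33, or 18 adjusted over the list alone (adjusted p = 4.2e-05). WNT targets rose in 5 of 16 with 1 lower (adjusted p = 0.00101), Axin2 among them by 0.31 ± 0.05, and cholesterol synthesis genes rose in 8 of 20 (adjusted p = 5.21e-05). General pluripotency genes fell in 8 of 15 by a median of -0.18 (adjusted p = 8.81e-16), Pou5f1 from 1790 ± 19.7 to 1560 ± 40.6 TPM. ERK and FGF targets fell in 4 of 18 (adjusted p = 6.48e-08), and the glycolysis list had 1 higher and 3 lower (adjusted p = 0.00444). The general pluripotency and the ERK and FGF lists also fell in untagged ESC with auxin. No list was tested with the untagged effect subtracted. Lists that rose in camera but were lost with an estimated correlation, that adjusted p in brackets, included neural progenitor (8 of 32 higher, 0.0663), Hedgehog (3 of 14, 0.0663), mesoderm (4 of 20, 0.0598), endoderm (4 of 17, 0.0598) and trophectoderm (6 of 14, 0.0538). The others were neural crest (3 of 12, 0.0598), imprinted (6 of 31, 0.293), cell-cycle inhibitors (2 of 10, 0.0583), p53 response (6 of 20, 0.171) and PRC1 (6 of 23, 0.273). Expressed Hox genes, 0 of 12 called and 3 higher adjusted over the list alone, did not pass (adjusted p = 0.408). The naive pluripotency and DNA methylation lists had medians of 0.01 and 0.05 while camera placed them below other genes (adjusted p = 0.408 and 0.0429, the latter 0.499 with an estimated correlation).

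In total 1031 of 15104 genes passed, 889 higher and 142 lower. With median-of-ratios scaling 995 passed, 428 higher and 567 lower, and 570 genes passed both ways, so which direction prevails depends on the scaling. Of all calls 38 changed at least 2-fold. Subtracting the untagged auxin effect left 29 genes, 27 higher and 2 lower. Pramel6 was among them, and Sp8, Gsc, Krt7, Dazl, Bmp4, Msx2, Tlx2 and Pitx1 were not. Of the calls 98.3% kept their sign in that test, and the median gene kept 83.4% of its change. The calls were chosen on the same auxin libraries, which favours a kept sign and size. Without untreated replicate 1, 2 or 3 the count was 586, 351 or 631, and without auxin replicate 1 or 2 it was 380 or 504. Voom called 2189, 1679 higher and 510 lower.

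The MTF2 degron line was examined for the same 12-hour effect. The lipid raft gene Rftn1 rose from 1.77 ± 0.323 to 4.72 ± 0.564 TPM (log2 1.21 ± 0.15, adjusted p = 0.00011), and the zinc finger gene Zfp703 from 2.28 ± 0.187 to 4.6 ± 0.659 TPM (0.87 ± 0.15). Homeobox gene Tlx2 rose from 16.9 ± 1.27 to 28.4 ± 2.71 TPM (0.73 ± 0.18, adjusted p = 0.0487). Dnmt3l, a cofactor of de novo DNA methylation, fell from 18.8 ± 3.18 to 9.84 ± 2.07 TPM (-0.91 ± 0.20, adjusted p = 0.0249). Bmp4 fell from 14 ± 1.48 to 6.75 ± 1.93 TPM (-1.03 ± 0.21), and the metalloprotease-like gene Adam23 by 1.05. Etv4, Spry4 and Utf1 fell by 0.83, 0.98 and 0.71. Cyp1a1 was listed at 0 in the 3 untreated libraries and measured 0.803 ± 0.132 TPM with auxin.

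Tlx2 was the 1 called gene of 70 Polycomb-target regulators, which did not pass as a list in MTF2 ESC (adjusted p = 0.561). General pluripotency genes fell in 6 of 15, or 8 adjusted over the list alone (adjusted p = 2.73e-11), and ERK and FGF targets in 2 of 18 (adjusted p = 2.19e-06). Both lists also fell in untagged ESC with auxin, and they were not tested with that effect subtracted. Aryl hydrocarbon receptor genes had 2 higher (adjusted p = 0.00116), the DNA methylation list 3 lower (adjusted p = 0.0017), the formative list 1 lower (adjusted p = 0.0141) and the neural crest list 0 called (adjusted p = 0.0499). With an estimated correlation their adjusted p was 0.142, 0.459, 0.142 and 0.142. Of 15104 genes 164 passed, 95 higher and 69 lower, and 11 changed at least 2-fold. With the untagged effect subtracted 1 gene passed, the thiolase gene Acaa2 (0.81 ± 0.13, adjusted p = 0.0402), chosen for naming after its value was seen; 885 genes were at an unadjusted p under 0.05. Of the calls 93.9% kept their sign, and the median gene kept 55.2% of its change. The count was 91 without untreated replicate 1, 95, 85 and 91 without auxin replicates 1, 2 and 3, and 26 in a fit to these 6 libraries alone.

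The same question in JARID2 degron stem cells gave the fewest calls of the tagged lines. Dppa3, a naive pluripotency gene also called Stella, rose from 151 ± 4.17 to 212 ± 11.8 TPM (log2 0.49 ± 0.06, adjusted p = 0.000353). The neural POU factor gene Pou3f1 fell from 9.01 ± 0.473 to 4.69 ± 0.553 TPM (-0.88 ± 0.15), and the Ras family gene Eras from 34.1 ± 2.17 to 20.5 ± 2.37 TPM (-0.72 ± 0.09). The growth regulator gene Myc fell from 20.7 ± 3.79 to 12.1 ± 2.75 TPM (-0.75 ± 0.15, adjusted p = 0.0299). Spry4, Id3 and Utf1 fell by 1.06, 0.64 and 0.59, and Plcg2 rose by 0.44, as in the untagged line. Cyp1a1 was 1.39 ± 0.577 TPM (24 reads) with auxin and 0.0589 ± 0.102 TPM (1 read) untreated. General pluripotency genes fell in 2 of 15, or 8 adjusted over the list alone (adjusted p = 1.32e-12). ERK and FGF targets fell in 3 of 18 (adjusted p = 4.71e-08), formative genes in 1 (adjusted p = 2.59e-05) and TGF-beta genes in 2 (adjusted p = 0.00267). All of these lists, general pluripotency included, were also called in untagged ESC with auxin. They were not tested with that effect subtracted. Naive pluripotency genes rose in 1 of 20, or 7 adjusted over the list alone (adjusted p = 0.00455, adjusted p = 0.334 with an estimated correlation). Retinoic acid genes had 0 called, with 3 lower adjusted over the list alone (adjusted p = 0.0261, adjusted p = 0.0552 with an estimated correlation). None of 70 Polycomb-target regulators was called by limma, and the list did not pass (adjusted p = 0.47). Of 15104 genes 45 passed, 17 higher and 28 lower, and 4 changed at least 2-fold. In limma 0 passed with the untagged effect subtracted, with 749 at an unadjusted p under 0.05 and the median called gene keeping 30% of its change, and 8 passed in a fit to these 6 libraries alone.

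Calls were compared between stem cell lines, whose untreated libraries are separate. The SUZ12 and MTF2 lines shared 56 higher genes against 5.6 expected (one-sided Fisher exact p = 1.95e-44) and 35 lower against 0.6 (exact p = 5.46e-54). SUZ12 and JARID2 shared 14 higher against 1 and 15 lower against 0.3. The untagged line and SUZ12 shared 7 of the 9 higher and 19 of the 23 lower genes of the untagged line. Genes higher in SUZ12 ESC, 889 with TPM scaling, were as a set higher in MTF2 ESC (79.2% positive, camera adjusted p = 3.7e-14) and in JARID2 ESC (74%, adjusted p = 7.7e-08). In untagged ESC 70.1% were positive (adjusted p = 3.6e-05). All 3 calls were lost with an estimated correlation, with an adjusted p of 0.0564, 0.141 and 0.249. Correlation of log2 changes across genes between SUZ12 and MTF2 ESC was 0.13. Genes are not independent replicates, so neither this correlation nor the exact p measures the spread between lines. The shared genes include those that auxin changed in the untagged line, and no overlap was tested with the untagged effect subtracted.

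The effect of auxin throughout differentiation of the SUZ12 degron line was examined in NPC. Nanog was 116 ± 0.308 TPM with auxin and 1.71 ± 0.93 TPM untreated (log2 5.79 ± 0.23, adjusted p = 7.89e-15). Pou5f1 was 341 ± 3.26 and 7.88 ± 0.953 TPM (5.36 ± 0.12, adjusted p = 3.69e-19), higher in 2 of 2 libraries. The germ cell gene Stra8 (chromosome 6, 34920163 to 34939344), which is needed for meiosis, rose from 4.47 ± 0.809 to 191 ± 8.85 TPM (5.28 ± 0.22). Dnmt3l, a cofactor of de novo DNA methylation, rose from 1.95 ± 0.59 to 127 ± 0.791 TPM (5.73 ± 0.32), and Osr1, a factor of intermediate and lateral mesoderm, from 0.769 ± 0.394 to 50.7 ± 6.29 TPM (5.37 ± 0.44). The Notch effector gene Hes5 (chromosome 4, 154960923 to 154962371) fell from 148 ± 11.1 to 5.57 ± 0.374 TPM (-4.61 ± 0.13, adjusted p = 1.09e-17), and the ventral homeobox gene Nkx6-2 from 432 ± 29.9 to 22.3 ± 0.269 TPM (-4.25 ± 0.07). Fabp7 fell from 334 ± 23 to 17.8 ± 2.71 TPM. The secretogranin gene Scg2 fell by 5.15, the motor neuron factor Lhx4 by 4.53 and the leucine-rich repeat gene Lrrn1 by 4.30. The precursor of the motor neuron microRNA Mir218-2 was listed at 0 with auxin and had 87 reads untreated.

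In SUZ12 NPC with auxin, naive pluripotency genes rose in 17 of 20 with 0 lower (median 3.92, adjusted p = 2.35e-12). General pluripotency genes rose in 14 of 15 with 1 lower (4.58, adjusted p = 6.28e-09), and germ line genes in 30 of 31 (2.53, adjusted p = 6.25e-15). Hox genes rose in 18 of 29 and fell in 6 (median 2.06, adjusted p = 0.000553). The trunk gene Hoxb9 was listed at 0 untreated and measured 12.1 ± 2.13 TPM with auxin, and the hindbrain genes Hoxa2, Hoxb3 and Hoxb2 fell by 2.36, 1.73 and 1.25. Mesoderm genes rose in 21 of 26 and fell in 3 (adjusted p = 1.22e-07), among them Meox1 (4.32 ± 0.17), Hand2 (4.09 ± 0.21) and Bmp4 (4.31 ± 0.24), with Tal1 falling by 3.06. Trophectoderm genes rose in 15 of 18 with 1 lower (adjusted p = 2.56e-07), and TGF-beta genes in 17 of 20 with 2 lower (adjusted p = 2.57e-07), Nodal by 4.91 and Lefty1 by 4.38. ERK and FGF targets rose in 16 of 20 with 1 lower (adjusted p = 1.24e-06). Two-cell-like genes rose in 8 of 9 (adjusted p = 0.00263), WNT targets in 9 of 17 with 3 lower (adjusted p = 0.00856). Aryl hydrocarbon receptor genes rose in 8 of 9 (adjusted p = 6.07e-06), Cyp1b1 by 3.07. Neuron genes fell in 28 of 30 with 1 higher (median -3.06, adjusted p = 7.39e-21), Isl1 by 3.59 and Nefl from 1030 ± 45.9 to 94.9 ± 7.88 TPM. Neural progenitor genes fell in 27 of 40 with 9 higher (adjusted p = 2.41e-06), Nes by 2.21. Cholesterol synthesis genes fell in 19 of 20 (adjusted p = 2.16e-07), Hmgcs1 from 538 ± 23.5 to 226 ± 6.08 TPM.

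Lists called in SUZ12 NPC but lost with an estimated correlation, that adjusted p in brackets, were Hedgehog (4 of 19 higher, 14 lower, 0.208), endoderm (14 of 23 higher, 5 lower, 0.208), imprinted (22 of 39 higher, 10 lower, 0.161) and proliferation (13 of 26 higher, 5 lower, 0.208). Imprinted H19 rose from 341 ± 12 to 2220 ± 30.3 TPM and Igf2 from 95.9 ± 2.95 to 528 ± 8.99 TPM, and Nnat fell from 1300 ± 36.9 to 203 ± 9.91 TPM. Polycomb-target regulators went both ways, 60 of 120 higher and 44 lower, and did not pass as a list (median 0.84, adjusted p = 0.151). Formative genes (8 higher, 4 lower, adjusted p = 0.172), neural crest genes (13 of 23 higher, 7 lower, adjusted p = 0.0836), retinoic acid genes (9 of 17 higher, 7 lower, adjusted p = 0.174) and p53 response genes (8 of 21 higher, 3 lower, adjusted p = 0.0723) did not pass either. Nor did cell-cycle inhibitors (3 higher, 3 lower, adjusted p = 0.783), PRC1 (4 of 23 higher, 8 lower, adjusted p = 0.728) and PRC2 subunits (5 of 12 higher, 4 lower, adjusted p = 0.164), and the PRC2 accessory gene Phf19 rose by 2.40 ± 0.18. Median, mean and test differed in sign for the unfolded protein stress (7 of 21 higher, 8 lower, adjusted p = 0.764), DNA methylation (6 of 23 higher, 12 lower, adjusted p = 0.734) and glycolysis (7 of 24 higher, 9 lower, adjusted p = 0.445) lists.

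Of 16469 genes 9368 passed, 3931 higher and 5437 lower, and 3699 changed at least 2-fold, 2025 upward. With median-of-ratios scaling 5075 were higher and 4244 lower, and voom gave 5476 and 4486, so the prevailing direction depends on the scaling. With the untagged effect subtracted 7170 passed, 6996 of them among the 9368. Sets were also defined in the untagged line, whose libraries are separate. Of 276 tested genes with the largest fall in differentiation, 261 were higher in SUZ12 NPC with auxin (median 2.92, camera adjusted p = 3.12e-47). Of 300 with the largest rise, 281 were lower and 11 higher (median -2.17, adjusted p = 2.12e-55). Both held with an estimated correlation. Genes with the largest fall are low in untreated NPC and can hardly go lower. Members were tested only if they reached 1 TPM in at least 2 NPC libraries, which drops those that stay off. The lean of that set to the higher side, in each NPC comparison, is therefore partly fixed in advance. The SUZ12 auxin group holds 2 libraries, and every value given for it rests on them.

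**Figure D2:**
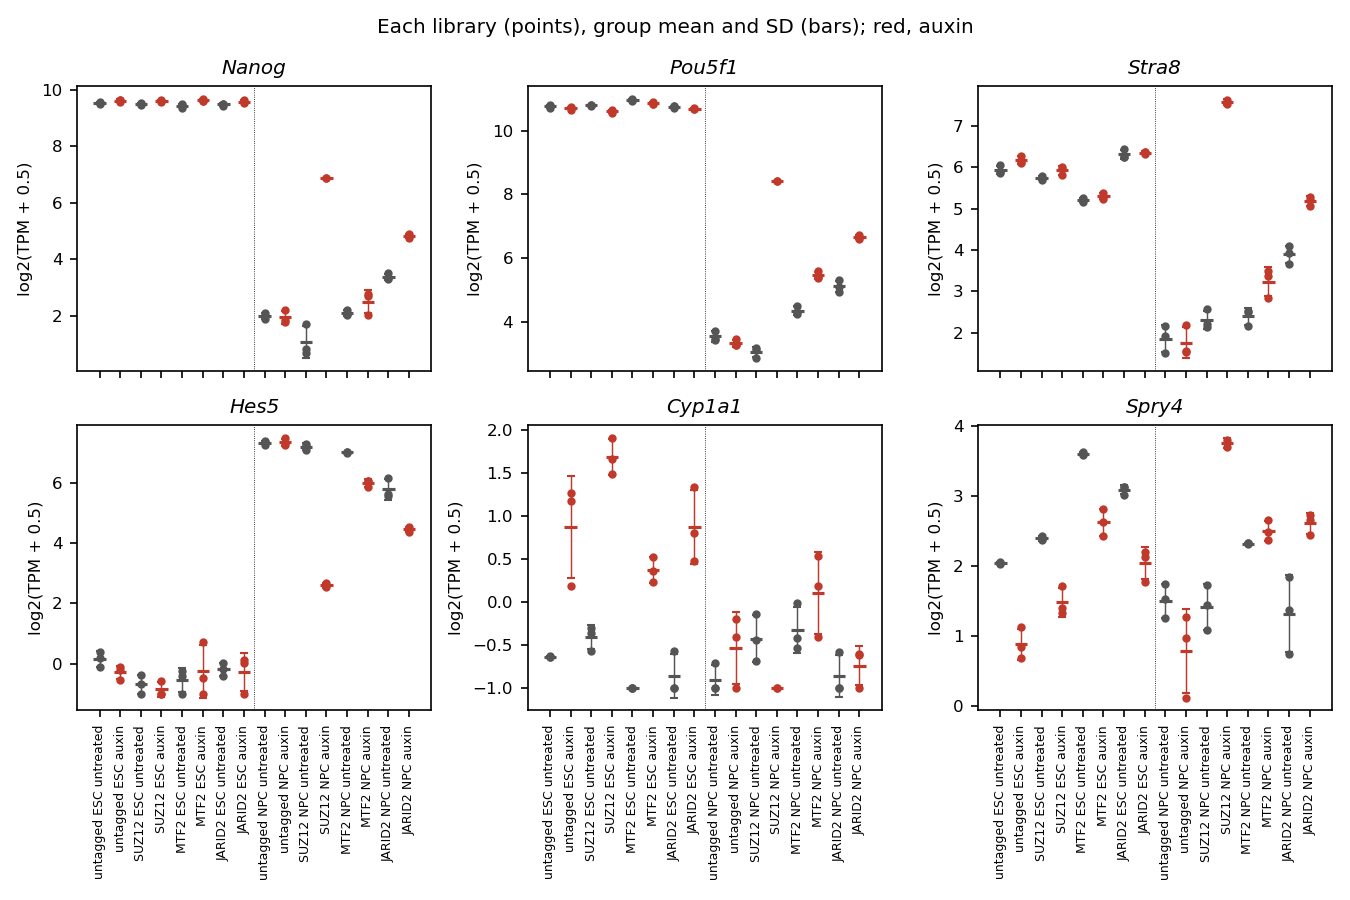
Log2(TPM + 0.5) of 6 genes in each of the 47 libraries (points, red for auxin), with group mean and SD as bars, by group on the x axis. Nanog, Pou5f1 and Stra8 are higher and Hes5 is lower in SUZ12 NPC with auxin than in untreated NPC, while Cyp1a1 is higher and Spry4 lower with auxin in all 4 ESC lines.

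The MTF2 degron line was examined after the same 5 days with auxin. The WNT agonist gene Rspo1 was 1.91 ± 0.429 TPM with auxin and 0.182 ± 0.159 TPM (2 reads) untreated. Pou5f1 rose from 20 ± 1.97 to 43.6 ± 3.62 TPM (log2 1.11 ± 0.10, adjusted p = 2.9e-06). The axon guidance receptor gene Robo3 fell from 3.87 ± 0.0585 to 0.977 ± 0.0694 TPM (-1.57 ± 0.19, adjusted p = 3.23e-05), and the interneuron progenitor gene Dbx1 from 5.81 ± 0.843 to 1.54 ± 0.725 TPM (-1.70 ± 0.39). Hes5 fell from 129 ± 1.45 to 63.6 ± 5.37 TPM (-1.02 ± 0.11). Precursor reads of Mir218-2 fell to 11 from 46. The hypoxia-induced gene Ndufa4l2 had 1 read with auxin and 4.28 ± 2.16 TPM untreated.

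Neuron genes fell in 18 of 30 with 1 higher, or 24 lower adjusted over the list alone (median -0.42, adjusted p = 7.26e-22), Nefl from 972 ± 37.9 to 677 ± 15.9 TPM. In untagged NPC with auxin the neuron list was also lower, by a median of -0.20. No list was tested with the untagged effect subtracted, so part of this fall may not need the degron. Endoderm genes rose in 13 of 23 with 0 lower (median 0.56, adjusted p = 4.9e-11), the basement membrane genes Lamb1 and Sparc by 0.75 and 0.38 and the lipid carrier gene Apoe by 0.70. General pluripotency genes rose in 6 of 15 (adjusted p = 6.75e-06), naive genes in 6 of 20 (adjusted p = 0.00383), and trophectoderm genes in 7 of 18 (adjusted p = 1.16e-05), Krt8 and Krt18 by 0.78 and 0.89. TGF-beta genes rose in 7 of 20 (adjusted p = 5.18e-05), p53 response genes in 6 of 21 (adjusted p = 0.00111), and the aryl hydrocarbon receptor list in 1 of 9, or 7 adjusted over the list alone (adjusted p = 0.00111). Called lists lost with an estimated correlation, that adjusted p in brackets, were imprinted (13 of 39 higher, 1 lower, 0.199), mesoderm (8 of 26 higher, 2 lower, 0.116), neural progenitor (6 of 40 higher, 12 lower, 0.199), retinoic acid (1 higher, 3 lower, 0.0511) and glycolysis (1 of 24 higher, 9 lower, 0.108), the last with Ldha falling from 484 ± 28.7 to 286 ± 8.08 TPM. Polycomb-target regulators (22 of 120 higher, 25 lower, adjusted p = 0.503) and Hox genes (2 of 29 higher, 5 lower, adjusted p = 0.227) did not pass. For both, and for the PRC1, neural crest and DNA methylation lists, median, mean and test differed in sign or were 0.

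Of 16469 genes 1340 passed in MTF2 NPC, 828 higher and 512 lower, and 179 changed at least 2-fold. With median-of-ratios scaling 728 were higher and 780 lower. In the sets from the untagged line, 51 of 276 falling genes were higher and 0 lower (median 0.42, camera adjusted p = 1.64e-09), and 99 of 300 rising genes were lower and 20 higher (median -0.22, adjusted p = 1.72e-23). With the untagged effect subtracted 230 passed, while 99.9% of the calls kept their sign and the median gene 89.4% of its change, and a fit to these 6 libraries alone called 601. The count was 788 without untreated replicate 2, 874 without untreated replicate 3 and 844 without auxin replicate 3.

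In NPC of the JARID2 degron line, Utf1 rose from 30.5 ± 6.85 to 125 ± 5.29 TPM (log2 2.04 ± 0.22, adjusted p = 7.25e-07), Pou5f1 from 34.4 ± 4.38 to 101 ± 4.38 TPM (1.54 ± 0.10). The epiblast growth factor gene Fgf5 rose from 0.299 ± 0.17 to 3.14 ± 0.287 TPM (2.20 ± 0.33), and the forebrain homeobox gene Hesx1 from 0.585 ± 0.681 to 4.08 ± 0.853 TPM (2.26 ± 0.48). The neurofilament genes Nefl and Nefm fell from 639 ± 69.9 to 152 ± 8.75 TPM (-2.06 ± 0.06) and from 297 ± 34.3 to 67.6 ± 4.39 TPM (-2.12 ± 0.07). Lhx4 fell from 12.5 ± 1 to 2.26 ± 0.605 TPM (-2.26 ± 0.12, adjusted p = 1.1e-11), and the metabotropic glutamate receptor gene Grm2 from 12.9 ± 2.42 to 2.36 ± 0.241 TPM. Shh, the floor plate morphogen gene, fell from 142 ± 10.3 to 59.3 ± 4.66 TPM (-1.26 ± 0.08), and Fabp7 fell by 1.58.

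Neuron genes fell in 29 of 30 (median -1.42, adjusted p = 1.49e-38), the lowest p of the 29 lists. General pluripotency genes rose in 13 of 15 (1.27, adjusted p = 5.92e-11), and naive genes in 13 of 20 with 1 lower (1.07, adjusted p = 1.67e-10). Formative genes rose in 10 of 15 with 3 lower (1.31, adjusted p = 4.21e-05), Otx2 and Dnmt3b by 1.93 and 1.37, and germ line genes in 11 of 31 (0.62, adjusted p = 2.35e-07). Trophectoderm genes rose in 10 of 18 with 1 lower (adjusted p = 8.33e-06), aryl hydrocarbon receptor genes in 7 of 9 (adjusted p = 9.62e-07), and TGF-beta genes in 8 of 20 with 2 lower (adjusted p = 0.000507). The cell-cycle inhibitor list fell in 6 of 10 (adjusted p = 0.00218), its cyclin gene Ccnd1 by 0.95. Called lists lost with an estimated correlation, that adjusted p in brackets, were ERK and FGF targets (9 of 20 higher, 1 lower, 0.0542), proliferation (8 of 26 higher, 0.0556), PRC2 (3 of 12 higher, 1 lower, 0.236) and neural progenitor (9 of 40 higher, 19 lower, 0.236). Others were Hedgehog (2 of 19 higher, 9 lower, 0.274), cholesterol synthesis (9 of 20 lower, 0.0848), two-cell-like (3 of 9 higher, 0.124) and retinoic acid (7 of 17 higher, 4 lower, 0.0791). Polycomb-target regulators (15 of 120 higher, 35 lower, adjusted p = 0.0643) and Hox genes (2 of 29 higher, 8 lower, adjusted p = 0.199) did not pass. For the imprinted and neural crest lists median and mean differed in sign.

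Of 16469 genes 4116 passed in JARID2 NPC, 1528 higher and 2588 lower, and 818 changed at least 2-fold. With median-of-ratios scaling 2175 were higher and 2235 lower, and voom gave 2234 and 2390, near even. In the untagged sets 153 of 276 falling genes were higher and 0 lower (median 1.01, camera adjusted p = 2.42e-36), and 254 of 300 rising genes were lower and 5 higher (median -0.83, adjusted p = 2.75e-70). With the untagged effect subtracted 1488 passed, 510 higher and 978 lower, while 99.7% of the calls kept their sign and the median gene 84.7% of its change.

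**Figure D3:**
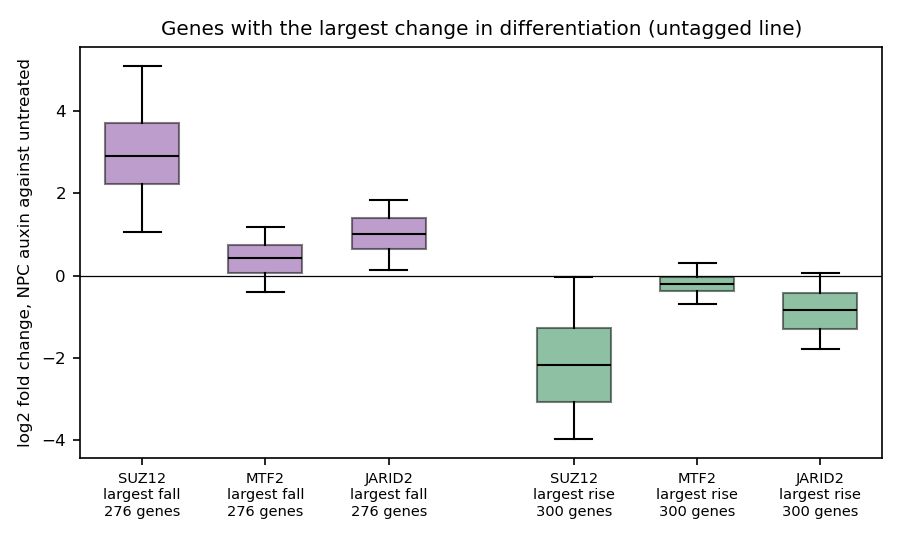
Log2 fold change with auxin in NPC (y axis) for the genes with the largest fall (purple) and largest rise (green) in differentiation of the untagged line, by degron line on the x axis; line, median; box, quartiles; whiskers, 5th and 95th percentiles. Medians of the falling genes are 2.92, 0.42 and 1.01 for SUZ12, MTF2 and JARID2, and those of the rising genes -2.17, -0.22 and -0.83.

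**Figure D4:**
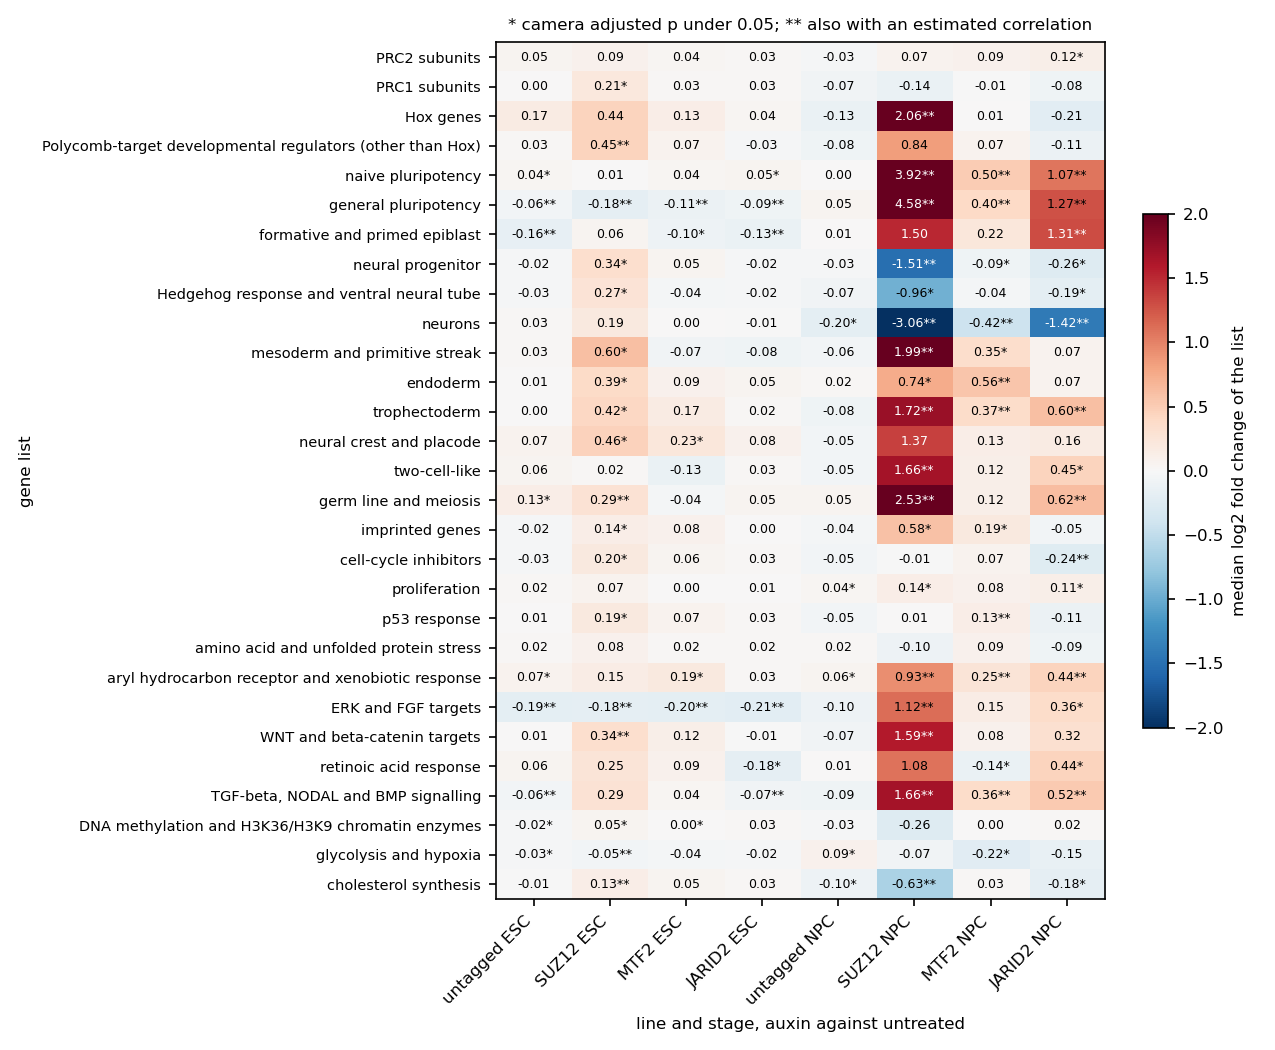
Median log2 fold change with auxin of each of the 29 gene lists (y axis) in the 8 line and stage comparisons (x axis), colour from -2 to 2, with 1 asterisk for a camera call and a pair for a call that also held with an estimated correlation. The neuron list is -3.06, -0.42 and -1.42 in SUZ12, MTF2 and JARID2 NPC and -0.20 in untagged NPC. The general pluripotency list is 4.58, 0.40 and 1.27 in SUZ12, MTF2 and JARID2 NPC.

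Calls of the NPC lines overlapped. SUZ12 and JARID2 shared 1273 higher genes against 364.7 expected and 2215 lower against 854.4. SUZ12 and MTF2 shared 577 higher against 197.6 (one-sided Fisher exact p = 1.55e-181) and 445 lower against 169 (exact p = 2.95e-146). MTF2 and JARID2 shared 329 against 76.8 (exact p = 1.91e-132) and 380 against 80.5 (exact p = 6.72e-200). The correlation of log2 changes across genes was 0.63 for SUZ12 and JARID2, 0.37 for SUZ12 and MTF2 and 0.26 for MTF2 and JARID2. Genes are not independent replicates, so neither these correlations nor the exact p values measure the spread between lines.

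Whether the auxin effect differed between stages was tested as a difference of contrasts, without subtracting the untagged effect. Auxin lasted 12 hours in ESC and 5 days in NPC, so stage and length of treatment cannot be told apart. For SUZ12 the effect was more positive in NPC than in ESC for Tdgf1, the NODAL co-receptor gene (6.13 ± 0.31), Dnmt3l (6.01 ± 0.39) and Nanog (5.67 ± 0.23), and more negative for Scg2 (-5.20 ± 0.27). It was also more positive for Suz12 (0.92 ± 0.15) and Jarid2 (0.92 ± 0.10). In all 8729 of 17760 genes differed, 3274 positive and 5455 negative, with a median over all genes of -0.153. Median-of-ratios scaling gave 4389 positive and 3951 negative and voom 4647 and 4310. Neuron genes were more negative in 28 of 30 (adjusted p = 1.07e-21) and naive pluripotency genes more positive in 17 of 20 (adjusted p = 8.49e-21). For MTF2, 527 genes differed, 294 positive and 233 negative (290 and 297 with median-of-ratios scaling), with Pou5f1 at 1.22 and Utf1 at 1.96 ± 0.22. A fit to these 12 libraries alone called 201 for MTF2, and voom 326. In the untagged line Utf1 changed by -0.70 in ESC and by 0.31 in NPC, the latter not called. For JARID2, 2672 genes differed, 1046 positive and 1626 negative (1397 and 1335 with median-of-ratios scaling, 1301 and 872 with voom, 1449 in all in a fit to these 12 libraries alone), with Nupr1, a stress-response gene, at 2.87 ± 0.56, Jarid2 itself at 0.67 ± 0.10 and neuron genes more negative in 27 of 30 (adjusted p = 3.56e-31).

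MTF2 and JARID2 mark alternative PRC2 forms, so their auxin effects were compared with each other. Each degron was carried by 1 line, so subunit, clone and extent of protein loss cannot be told apart. The lines also differed before auxin: in untreated NPC, Tubb3 was 2150 ± 69.7 TPM in the MTF2 line and 1310 ± 125 TPM in the JARID2 line. Hes5 was 129 ± 1.45 and 55.9 ± 14 TPM. In ESC, 0 of 15104 genes differed in limma, with 898 at an unadjusted p under 0.05 and 0 in voom, and no list passed. The count was 1 without MTF2 untreated replicate 3 and 1 without JARID2 untreated replicate 2. In NPC 1588 genes differed, 1288 more positive and 300 more negative in the MTF2 line. Neuron genes were more positive in the MTF2 line in 25 of 30 (median 1.13, adjusted p = 1.04e-35), Gap43 by 1.27 ± 0.07 and Nefl by 1.54 ± 0.09. Shh (1.68 ± 0.11) and Ccnd1 (0.90 ± 0.06) were likewise more positive, and the cell-cycle inhibitor list, which holds Ccnd1, differed in 4 of 10 (adjusted p = 0.000129). Naive pluripotency genes were more negative in 6 of 20 with 1 more positive (adjusted p = 4.07e-06), Esrrb by -1.24 ± 0.29. Formative genes were more negative in 5 of 15 (adjusted p = 4.07e-06), Dnmt3b by -0.76 ± 0.13, and germ line genes in 3 of 31 (adjusted p = 4.07e-06). Polycomb-target regulators differed in 27 of 120 positively and in 7 negatively (adjusted p = 0.0205, adjusted p = 0.363 with an estimated correlation). A fit to these 12 libraries alone called 996.

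Tagged lines were compared with the untagged line without auxin to measure what the auxin comparisons start from. Each tag was carried by 1 line, so tag and clone are the same variable. Suz12 RNA in the SUZ12 line was 285 ± 29.5 TPM against 145 ± 3.08 TPM in ESC (log2 0.97 ± 0.09, adjusted p = 1.88e-06) and 77.8 ± 1.5 against 36.9 ± 1.08 TPM in NPC (1.07, adjusted p = 2.43e-06). In that line the imprinted gene Peg10 was lower in ESC (3.22 ± 0.373 against 8.92 ± 0.821 TPM, -1.34 ± 0.13), and the imprinted noncoding RNAs Meg3 and Rian were lower in NPC (-1.71 ± 0.16 and -2.04 ± 0.18). SUZ12 calls were 249 in ESC, 71 higher and 178 lower, and 134 in NPC, 110 higher and 24 lower. The ESC count was 67, 106 or 147 without untagged replicate 1, 2 or 3 and 113, 82 or 115 without SUZ12 replicate 1, 2 or 3. The NPC count was 89 or 83 without untagged replicate 2 or 3 and 81 or 83 without SUZ12 replicate 1 or 2.

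In the MTF2 line the Y-linked translation factor gene Eif2s3y was listed at 0 in the 3 untreated ESC libraries and measured 13.9 ± 1.8 TPM in the untagged line, and Ddx3y was listed at 0 against 7.65 ± 0.862 TPM. The prohormone-processing gene Cpe on chromosome 8 was higher (12.3 ± 1.8 against 2.64 ± 0.363 TPM, 2.03 ± 0.20), and Mtf2 RNA was lower (52.1 ± 4.8 against 65.1 ± 2.56 TPM, -0.32 ± 0.08, adjusted p = 0.00504). Suz12 RNA, whose gene is not tagged in this line, was lower as well (113 ± 10.2 against 145 ± 3.08 TPM, -0.36 ± 0.09, adjusted p = 0.00576). MTF2 calls were 2372 in ESC, 1105 higher and 1267 lower, and 1443 in NPC, 1020 higher and 423 lower, among them the heart and sympathetic factor Hand2 (2.21 ± 0.19). The NPC count was 917 or 760 without untagged replicate 2 or 3. JARID2 calls were 953 in ESC, 466 higher and 487 lower, Jarid2 RNA among the latter (95.6 ± 3.97 against 112 ± 2.4 TPM, -0.23 ± 0.05, adjusted p = 0.00479). In NPC they were 3923, 1950 higher and 1973 lower. With median-of-ratios scaling the splits were 542 and 461 in ESC and 2206 and 1981 in NPC. Dnmt3l was higher (11.2 ± 2.41 against 1.4 ± 0.834 TPM, 2.73 ± 0.29), as was the endocytic receptor gene Cubn (2.66 ± 0.21). Tal1, a factor of spinal interneurons and blood, was lower (1.7 ± 0.479 against 14.5 ± 2.13 TPM, -2.78 ± 0.17).

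Untreated NPC of the JARID2 line already differed from untagged NPC in the sets from differentiation. Of 276 genes with the largest fall, 114 were higher and 1 lower (median 0.80, camera adjusted p = 2.01e-21). Of 300 genes with the largest rise, 206 were lower and 27 higher (median -0.55, adjusted p = 9.08e-31). Both held with an estimated correlation. These sets were chosen in the untagged libraries compared here; sets chosen in the auxin libraries of the untagged line, a test added after seeing the data, had medians of 0.76 and -0.55. In untreated MTF2 NPC 37 falling genes were higher and 1 lower (median 0.22, adjusted p = 0.000653, adjusted p = 0.0528 with an estimated correlation). There 41 rising genes were lower and 29 higher (median -0.05, adjusted p = 0.000324, adjusted p = 0.407 with an estimated correlation).

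**Figure D5:**
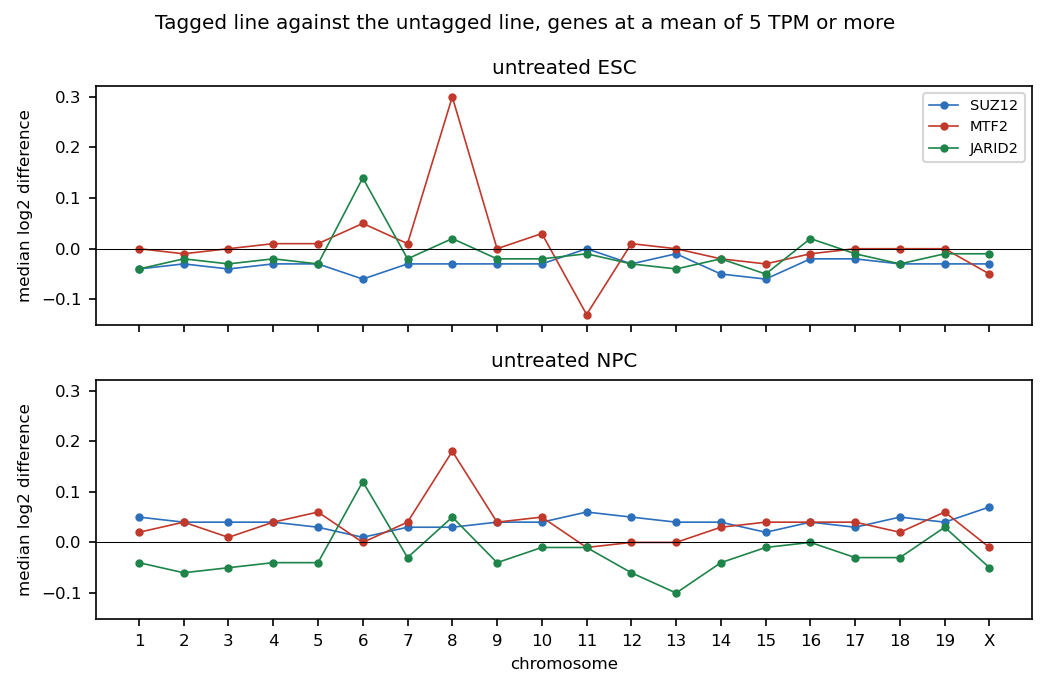
Median log2 difference from the untagged line of genes at a mean of 5 TPM or more (y axis), by chromosome (x axis), for untreated ESC above and untreated NPC below; each point is 1 chromosome of 1 tagged line. Chromosome 8 of the MTF2 line is at 0.30 and 0.18, and chromosome 6 of the JARID2 line at 0.14 and 0.12.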

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

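Tests of stem cell mixing, of a degron-free auxin response, of aryl hydrocarbon receptor targets, of chromosome copies as the whole cause in the MTF2 line and of reduced JARID2 function were chosen after the result was seen; the others in this part were written before. The first results here were singled out by a difference between groups, tested as a contrast of auxin effects. Auxin in untagged ESC and the untreated lines, given last, were not, and are weighed because the auxin comparisons rest on them. Between NPC and ESC, stage and length of auxin treatment cannot be told apart. The effect of auxin differed between NPC and ESC for 8729 genes in the SUZ12 line, 527 in the MTF2 line and 2672 in the JARID2 line. It differed from that of the untagged line for 29 genes in SUZ12 ESC, 1 in MTF2 ESC, 7170 in SUZ12 NPC, 230 in MTF2 NPC and 1488 in JARID2 NPC. Between the MTF2 and JARID2 lines it differed for 1588 genes in NPC. Gap43, the neuronal growth cone gene, is among them, falling by 0.47 on the log2 scale in MTF2 NPC and by 1.74 in JARID2 NPC. Subunit and clone cannot be told apart between these lines.

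Of 100 splits of the 12 libraries, 4 gave as many genes as the 527 of MTF2 and 3 as many as the 2672 of JARID2, the real split included, with 779 and 2907 in the highest other split. These shares are under 0.05. For the 1588 genes between MTF2 and JARID2 NPC 10 of 100 splits gave as many, the highest other being 4144. The splits shuffled auxin labels within each stage or line, which removes the auxin effect along with its difference. They therefore cannot decide whether chance made the difference. All 3, 2 and 9 other splits that were as large left the treatment labels of 1 stage or line whole, as 24 of the draws do, so they carry a real auxin effect of the samples and not noise alone. The SUZ12 difference between stages has a group of 2 libraries and was not split.

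Genes lost in differentiation were higher in SUZ12 NPC with auxin, among them Nanog and Pou5f1. Unaltered stem cells mixed in would raise each by a similar share of its stem cell level, with a ratio of the 75th to the 25th percentile under 2. Over 234 genes that ratio was 3.34 (median share 16.6%, 10th percentile 3.54%, 90th 50.8%), which argues against mixing of unaltered stem cells as the whole cause. Undifferentiated cells whose levels changed during the 5 days are not covered by this test. With median-of-ratios scaling 100% of the genes stayed called, and with the untagged auxin effect subtracted 93.9% did, which argues against the scaling of the values and against auxin itself. A candidate explanation left open is that cells without SUZ12 may shut these genes down incompletely or in part of the culture, which bulk RNA does not separate.

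The 32 genes changed by auxin in untagged stem cells, such as Spry4, Utf1 and Cyp1a1, pose the question whether auxin acts without a degron. Of them 27 had the same direction in all 3 tagged lines, against 4 by chance, so a degron-free response is a candidate cause for these genes. Handling of treated dishes is confounded with auxin and cannot be told apart from it. Aryl hydrocarbon receptor activation cannot be told apart from other routes either, since only 2 of the 32 are on that list. As a set they did not repeat it in 5-day NPC cultures, where 17 of 31 had the ESC direction with a median of 0.01, against a median size of 0.38 in ESC, but Spry4 at -0.72, Parvb at -0.25 and Pdzd4 at -0.19, chosen after their values were seen and not called, went in the ESC direction and Cyp1a1 was too low to test.

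The MTF2 and JARID2 lines differed from the untagged line without auxin. For MTF2, an extra chromosome 8 in part of the cells is a candidate cause: its genes had median differences of 0.30 in ESC and 0.18 in NPC untreated and at least 0.23 in auxin libraries, and 333 of 345 called chromosome 8 genes at a mean of 5 TPM or more were higher in ESC, but only 15.6% of all its calls in ESC and 13% in NPC lie on chromosome 8 or Y, which argues against dosage of their own genes as the whole cause. An extra chromosome 6 in part of the JARID2 cells cannot be told apart from other line differences, the lower median in auxin libraries being 0.08, and only 5.7% of the genes called in JARID2 NPC lie on chromosome 6 or Y, which argues likewise there. Chromosome 8 held 113 of the 953 JARID2 calls in ESC and chromosome 6 held 97; on chromosome 8 86 of 107 called genes at 5 TPM or more were higher but the medians were 0.02 in ESC and 0.05 in NPC, for which no explanation was tested. Reduced JARID2 function without auxin is left open: genes higher in SUZ12 NPC with auxin had a median of 0.24 in untreated JARID2 NPC, a test that replaced one in ESC after its value of -0.04, against it, was seen, while genes lost in differentiation had 0.80 and rising genes -0.55, so any poorer differentiation of this clone may raise that set too.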

How the results depend on the processing

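The voom test, the test without very short genes and the sets chosen in auxin libraries were chosen after seeing the data; the other alternatives were planned. Of 20 total counts of calls, higher and lower genes together, all stayed within 1.5 times the reported count with a pseudocount of 0.1 or 1, with median-of-ratios scaling and without very short genes. Voom kept 14, no filter 18, a fit to the compared groups alone 9 and replicate number as a block 5. Where a count moved, the cause was not tested, except that the 2-fold requirement can only lower a count by construction.

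The balance of higher and lower genes moved where totals did not. Median-of-ratios scaling turned it from 889 and 142 to 428 and 567 in SUZ12 ESC, from 3931 and 5437 to 5075 and 4244 in SUZ12 NPC, and from 828 and 512 to 728 and 780 in MTF2 NPC. The differences between stages became 4389 and 3951 for SUZ12, 290 and 297 for MTF2 and 1397 and 1335 for JARID2, and untreated JARID2 became 542 and 461 in ESC and 2206 and 1981 in NPC. JARID2 NPC came near even at 2175 and 2235, and differentiation at 7101 and 6350 kept its majority. Voom turned SUZ12 NPC (5476 and 4486), the stage differences of SUZ12 (4647 and 4310) and JARID2 (1301 and 872) and untreated JARID2 ESC (584 and 569). Median-of-ratios scaling multiplies all genes of a library by 1 factor, so by construction genes with small changes can change side. At least a 2-fold change turned SUZ12 NPC (2025 and 1674), MTF2 ESC (5 and 6) and untreated SUZ12 ESC (8 and 6), JARID2 ESC (27 and 23) and JARID2 NPC (501 and 272), and left untagged ESC even at 1 and 1. A fit to the compared groups alone turned untagged ESC (15 and 10), MTF2 ESC (11 and 15) and untreated JARID2 ESC (252 and 200), and left JARID2 ESC even at 4 and 4. The block turned untagged ESC (9 and 6), the JARID2 stage difference (583 and 555) and untreated SUZ12 ESC (9 and 2), MTF2 ESC (450 and 442), JARID2 ESC (208 and 140) and JARID2 NPC (1289 and 1281), and no filter untreated JARID2 ESC (398 and 394). Of libraries left out, MTF2 auxin replicate 2 turned MTF2 ESC (39 and 46), JARID2 untreated replicate 1 JARID2 ESC (20 and 14), and 5 libraries untreated JARID2 ESC and 3 untreated JARID2 NPC.

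Requiring a change of at least 2-fold left 2, 38, 11 and 4 genes in untagged, SUZ12, MTF2 and JARID2 ESC, 3699, 179 and 818 in SUZ12, MTF2 and JARID2 NPC, and 7821 in differentiation. It left 3994, 146 and 809 genes with a difference between stages, 399 between MTF2 and JARID2 NPC, 14, 152 and 50 in untreated SUZ12, MTF2 and JARID2 ESC against the untagged line, and 43, 147 and 773 in NPC. The exact p of shared lower genes in ESC became 1 for each of the 3 pairs of tagged lines.

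A fit to the compared groups alone called 26 genes in MTF2 ESC, 8 in JARID2 ESC, 4 in untagged NPC and 601 in MTF2 NPC. It called 201 and 1449 for the differences between stages of MTF2 and JARID2, 996 between MTF2 and JARID2 NPC, 139, 1523 and 452 in untreated SUZ12, MTF2 and JARID2 ESC and 806 in untreated MTF2 NPC. Voom called 57 in untagged ESC, 2189 in SUZ12 ESC, 16 in untagged NPC, 326 for the MTF2 difference between stages, and 569 and 340 in untreated SUZ12 ESC and NPC. Without a filter 1 gene was called in untagged NPC and 2 between MTF2 and JARID2 ESC.

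Replicate numbers do not pair the samples: correlations of same-numbered libraries ran from -0.10 in SUZ12 ESC to 0.20 in untagged NPC, and no comparison had all pairs over 0.1. With replicate as a block 15, 39, 0 and 0 genes were called in untagged, SUZ12, MTF2 and JARID2 ESC, and 173 and 2233 in MTF2 and JARID2 NPC. The block was fitted to the compared groups alone, which leaves few libraries to estimate the spread from. A lower count therefore need not come from replicate effects. The MTF2 and JARID2 differences between stages had 57 and 1138, and MTF2 against JARID2 NPC 823. Untreated lines had 11, 892 and 348 in ESC and 32, 245 and 2570 in NPC. The counts of 0 are limma's; main limma counts were 164 and 45, with 1697 and 1402 genes at an unadjusted p under 0.05. For SUZ12 NPC the block by title or by library name gave 8251 or 8045.

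Over the libraries left out 1 at a time, where at least 1 of them moved the count by over 1.5 times, 18 to 24 genes were called in untagged ESC, 351 to 733 in SUZ12 ESC, 85 to 158 in MTF2 ESC, 0 to 2 in untagged NPC, 788 to 1135 in MTF2 NPC and 0 to 1 between MTF2 and JARID2 ESC. For untreated lines the ranges were 67 to 147 in SUZ12 ESC, 81 to 101 in SUZ12 NPC and 760 to 1441 in MTF2 NPC. The libraries are named with each count above. SUZ12 NPC ran from 7875 to 8843; where 1 of its 2 auxin libraries is left out, the lone library is assumed to vary like the other groups.

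Subtracting the untagged auxin effect left 29 genes in SUZ12 ESC, 1 in MTF2 ESC, 0 in JARID2 ESC (749 at an unadjusted p under 0.05 in limma), 230 in MTF2 NPC and 1488 in JARID2 NPC. It reversed the log2 change in 10 results for named genes, some of them the same gene in several lines. In SUZ12 ESC Spry4 went to 0.245, Utf1 to 0.076, Id3 to 0.061 and Nqo1 to -0.099. In MTF2 ESC Spry4 went to 0.181, Id3 to 0.013 and Cyp1a1 to -0.133. In JARID2 ESC Spry4 went to 0.108, Utf1 to 0.106 and Enox1 to 0.055. All are genes that auxin changed in untagged ESC, so the subtraction removes their shared part.

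For gene lists, an estimated correlation ended 50 of 261 results and changed the side of no other, fry ended 11 and added 35, and median-of-ratios scaling ended 7 and added 5. Fry reversed 5, each called against the camera direction: Polycomb-target regulators in SUZ12 NPC (1.3e-06; other alternatives 0.518 to 0.596), and in differentiation the formative (3.61e-10; 0.565 to 0.617), mesoderm (1.19e-08; 0.747 to 0.903), endoderm (1.6e-12; 0.836 to 0.91) and TGF-beta lists (2.51e-08; 0.631 to 0.806). Fry asks whether the members changed and camera whether they changed more than other genes. The proliferation list in SUZ12 ESC reversed with median-of-ratios scaling (0.0246; other alternatives 0.0451 to 0.897); the cause was not tested.

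For sets, all as adjusted p, the estimated correlation gave 0.249 for SUZ12 ESC higher genes in untagged ESC (fry 0.057), 0.0564 and 0.141 for them in MTF2 and JARID2 ESC (called by fry), 0.0607 and 0.0988 for genes of largest rise and fall in SUZ12 ESC (fry 0.31 for the fall), 0.142 for genes of largest rise in JARID2 ESC (fry 0.248), and 0.419 and 0.495 for SUZ12 ESC higher genes in untagged and MTF2 NPC (fry 0.211 and 0.0574). Fry gave 0.211 for SUZ12 NPC higher genes in untagged NPC, and 0.0123 for SUZ12 ESC higher genes in JARID2 NPC, which camera did not call. With 100 genes the largest-rise set in SUZ12 ESC reached 0.17. In untreated JARID2 NPC, sets chosen in auxin libraries of the untagged line had medians of 0.76 and -0.55, against 0.80 and -0.55. The cause was not tested.

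Among 779 results for named genes, 10109 of 11609 alternatives kept direction and side of the threshold, 1487 kept the direction but were no longer called (356 results at least once), 3 became called and 10 reversed. Most of these genes were named because they were called in the same libraries, which favours a kept direction and leaves few that could become called. The block ended 277, the subtraction 238 of 526, compared groups alone 135, voom 68 and leaving out a library 664 of 4785. Depth limits low genes: a gene at 1 TPM has few reads per library. In simulated MTF2 ESC data 47.8% of genes changed 1.5-fold were recovered and 90.9% of those changed 4-fold, while 12.2% of calls were false.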

Other observations

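In SUZ12 NPC with auxin some genes stood above their level in both stages of the untagged line; these were chosen for this description after their values were seen. The imprinted growth regulators H19 and Igf2 measured 2220 ± 30.3 and 528 ± 8.99 TPM (n = 2), against 1.34 ± 0.138 and 0.531 ± 0.097 TPM in untreated untagged ESC and 211 ± 2.84 and 49.9 ± 2.51 TPM in untreated untagged NPC (n = 3 each). The epithelial keratin Krt18 was 515 ± 37.6 TPM against 8.01 ± 2.54 and 51.6 ± 4.99 TPM, and the somite factor Meox1 124 ± 1.19 TPM against 1 read and 4.47 ± 0.702 TPM. The mesoderm factor Osr1 was 50.7 ± 6.29 TPM, listed at 0 in untagged ESC and 0.358 ± 0.184 TPM in untagged NPC. Meiotic Stra8 was 191 ± 8.85 TPM against 60.5 ± 4.41 TPM in untagged ESC and 3.18 ± 0.806 TPM in untagged NPC. The untagged line is another clone, so part of the distance from it may not come from auxin. Against untreated NPC of the SUZ12 line itself, H19 rose by 2.7 and Igf2 by 2.46 on the log2 scale.

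Where 3 libraries are compared with 3, there are 10 splits, too few for a share under 0.05. In untagged, SUZ12, MTF2 and JARID2 ESC with auxin, the real split called 32, 1031, 164 and 45 genes, and the highest other split 0, 0, 2 and 1. In MTF2 and JARID2 NPC with auxin the real split called 1340 and 4116 and the highest other 1 and 1, and in differentiation 13517 and 0. Untreated SUZ12, MTF2 and JARID2 lines against the untagged line had 249, 2372 and 953 in ESC with 0, 1 and 1 in the highest other, and 134, 1443 and 3923 in NPC with 2, 2 and 1. In each of these 1 of the 10 splits, the real one, was as large. In untagged NPC with auxin limma called 0 genes in the real split (1180 at an unadjusted p under 0.05, voom 16) and 1 in the highest other, so 10 of 10 were as large. Between the MTF2 and JARID2 effects in ESC, limma called 0 (898 at an unadjusted p under 0.05, voom 0), all 100 splits gave as many, and the highest other gave 296. SUZ12 NPC with auxin has 2 libraries and was not split.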
